A study of Picromerus lewisi with 6 samples.

How the data were processed

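Picromerus lewisi is a stink bug of the family Pentatomidae that preys on insects. Its venom glands were sampled from adults and from nymphs of the 5th instar, with 3 libraries per stage. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit. The labels do not say whether the libraries came from separate animals or pools, so p-values measure only the spread between these libraries, which may be technical.

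The deposited values are FPKM (fragments scaled by cluster length and by the fragments mapped in the library), 1 column per library, for 22242 transcript clusters with a median length of 589.5 bases, the longest of 13462 bases. Per the submitters' processing notes, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used, with no role or order given. The identifiers have the form of clusters from a transcript assembly, and which tool gave the FPKM is not given in the sources used here. No genome was used here, so clusters carry no genomic position. The deposited table gives best matches in protein and nucleotide databases. A protein match was present for 13413 clusters, and 11526 received a name from the protein, Swiss-Prot, KO or mRNA description, in that order. Cluster names are therefore names of the best match, and several clusters can be fragments or copies of 1 gene whose reads could not be told apart.

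Depth was recovered from the FPKM, whose low values move in steps of 1 fragment. For each library, the total of mapped fragments and a length offset were fitted on clusters of 500 to 1100 bases with FPKM below 3, so that the product of FPKM, total and shortened length came out whole. The offsets were 287, 243 and 278 bases in adult replicates 1, 2 and 3 and 217, 293 and 293 in nymph replicates 1, 2 and 3. The FPKM thus divide by length less an offset that differs between libraries. This weighs most on short clusters, whose FPKM compare less well between libraries. In clusters of at least 400 bases, 13334175, 13905395 and 17629052 fragments were recovered for adult replicates 1, 2 and 3, and 13348269, 18656695 and 17487671 for nymph replicates 1, 2 and 3. In clusters of 1100 to 1500 bases that were left out of the fit, 99.4% to 99.8% of values lay within 0.15 of a whole fragment, against 30.0% by chance. The procedure was tested on simulated data first. Intervals and limits from these totals would cover counting error only, and none is given.

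The stages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust), on log2(rescaled FPKM + 1), with stage as the only term and adult minus nymph as the direction. Libraries were rescaled by the median ratio to the geometric mean over 4653 clusters above 0 in all 6 libraries. The factors were 0.2835, 1.643 and 1.559 in adult replicates 1, 2 and 3 and 1.022, 1.361 and 0.9902 in nymph replicates 1, 2 and 3. Clusters entered with FPKM of at least 1 in at least 3 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a second count also asked for a fold of at least 2. Fold changes are on the log2(value + 1) scale, which understates the change of low clusters. On simulated data with the spread of these libraries and 11961 clusters, the test for adult minus nymph recovered 0 of 50 clusters changed 2-fold, 1 of 50 changed 4-fold, 22 of 50 changed 16-fold and 29 of 50 changed 64-fold, with 0 false calls. With a smaller spread there were 10 false calls. The simulated noise was independent between clusters, without the unequal detection of whole libraries, so the 0 does not bound false calls in these data.

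Gene lists, 23 in all, were fixed as text patterns on the descriptions before the data were examined, as were the tests, the rule for named genes and most alternatives. A pattern can match any of several protein descriptions of a cluster, so some members do not carry the list's name. Each list was tested with camera from limma at its preset correlation of 0.01, with at least 5 tested clusters, and adjusted over the lists. Shares of total FPKM were compared by an exact two-sided permutation test over the 20 assignments, whose smallest possible p is 0.1. The text names the 10 largest rises and the 10 largest falls past the threshold with a mean FPKM of at least 10 in the higher stage, no overlap between stages and a naming description. It also names the 10 most abundant clusters and, per list, the 2 most abundant members and the largest rise and fall past the threshold with a mean FPKM of at least 5. Clusters named outside that rule are marked as chosen after their values were seen. Fewer than 10 clusters met the rule in each direction.

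The alternatives were pseudocounts of 0.1 and 0.5, other filters, FPKM as deposited, rescaling to an equal total, quantile normalization, limma without trend and robust, a replicate block, each library left out, camera with an estimated correlation, fry, lists without their most abundant member, other detection thresholds, shares weighted by cluster length, and limma-voom on the recovered fragments of clusters of at least 400 bases. Library quality weights, removal of clusters matching moths or mouse, lists matched with Pfam as well, and shares outside mitochondrial clusters were added after seeing the data. So were the definitions and score minimums of the moth and mouse sets, and the moth set was restricted to non-mitochondrial matches after its values were seen. The host mitochondrial set holds 34 clusters matching Picromerus lewisi mitochondrial sequence. The noctuid set holds 95 non-mitochondrial clusters whose best nucleotide match is a moth of the family Noctuidae, with a score of at least 100 and no best protein match in Hemiptera. The mouse set holds 56 clusters matching mouse with a score of at least 70% of the cluster length and no best protein match in Hemiptera. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.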

Results

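Gene expression was profiled in the venom glands of Picromerus lewisi, a stink bug that injects salivary venom into its insect prey. The series compared 3 adult libraries with 3 libraries of 5th-instar nymphs, and asked how the gland transcriptome differs between the stages. From the FPKM, 13334175 to 18656695 fragments per library were recovered in clusters of at least 400 bases.

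By mean FPKM over the 6 libraries, the most abundant clusters were mitochondrial, with a serine protease among the leading 10. Adult replicate 2 differed, with 32.5% of FPKM in serine proteases and 18.6% in host mitochondrial clusters. Among the 10 clusters with the highest mean FPKM, 5 encoded cytochrome c oxidase subunits, the terminal enzyme of the respiratory chain. They were Cluster-9520.4335, Cluster-9520.4346 and Cluster-9520.4355 (subunit 1) and Cluster-9520.4394 and Cluster-9520.4383 (subunit 2). Cluster-9520.4356 and Cluster-9520.4352, unnamed and matching the bug's own mitochondrial genome, stood above all of them. Their FPKM was 946409 and 893756 in adult replicate 1 and 117387 and 92760 in adult replicate 2. Cluster-9520.4468, whose best nucleotide match is a moth mitochondrial genome, and the unnamed Cluster-9520.4306 completed the top group with Cluster-9520.4333, a venom serine protease 34. The FPKM of Cluster-9520.4333 was 20292, 140337 and 23045 in adult replicates 1, 2 and 3 and 10994, 21222 and 6065 in nymph replicates 1, 2 and 3. A further venom serine protease, Cluster-9520.4416, reached 80495 FPKM in adult replicate 2 and 4200 in nymph replicate 3.

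Host mitochondrial clusters took 84.6%, 18.6% and 74.3% of total FPKM in adult replicates 1, 2 and 3 and from 52.7% to 71.2% in the nymph libraries (exact permutation p = 1.0, n = 3 per stage). The 10 most abundant clusters held 73.3% ± 24.8 (SD, n = 3) of FPKM in adults and 78.2% ± 7.76 in nymphs (exact permutation p = 1.0). The 100 most abundant held 93.6% ± 5.95 in adults and 93.1% ± 2.37 in nymphs (exact permutation p = 0.8, n = 3). The leading host mitochondrial clusters, Cluster-9520.4356 and Cluster-9520.4352, were short, at 458 and 421 bases. FPKM divides by length less an offset, which raises the weight of such short clusters. The shares in this paragraph are therefore shares of FPKM and not of fragments. Clusters with FPKM of at least 1 numbered 4927, 18155 and 8679 in the adult libraries and 14040, 10862 and 11693 in the nymph libraries (exact permutation p = 0.8, n = 3 per stage). Adult replicate 2 thus stood apart from adult replicates 1 and 3 in both measures. Of 96 clusters for cytosolic ribosomal proteins that match neither moth nor mouse, proteins which every cell uses, 5 to 13 were listed at 0 in each library, so an entry of 0 is given here only as listed at 0.

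**Figure D1:**
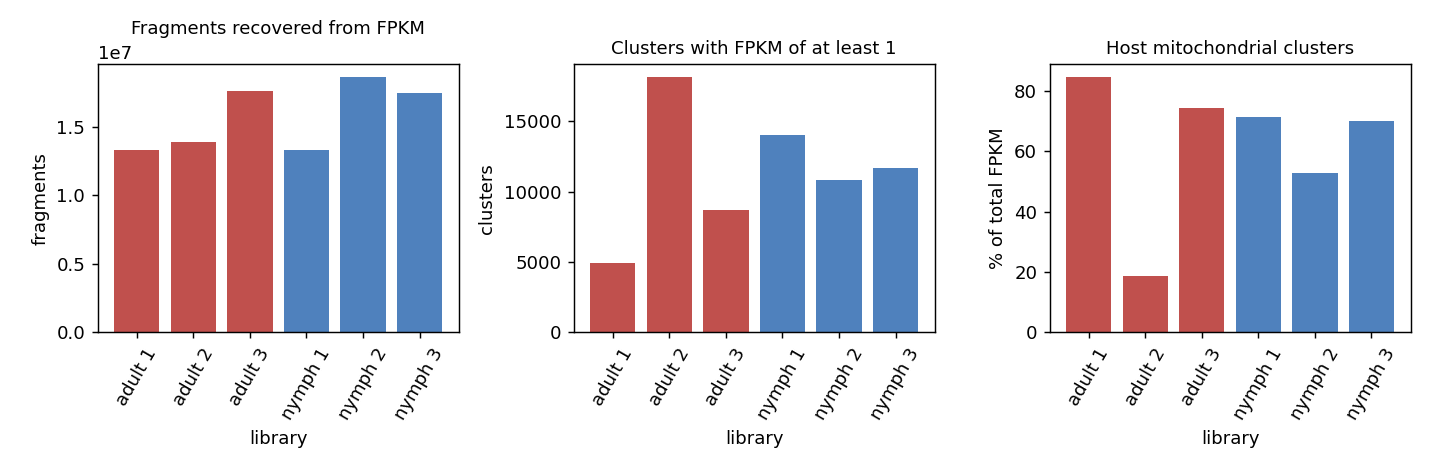
Bars give, for each of the 6 libraries (adult in red, nymph in blue), the fragments recovered in clusters of at least 400 bases, the number of clusters with FPKM of at least 1, and the percent of total FPKM in host mitochondrial clusters. Fragments ranged from 13334175 to 18656695, while the clusters detected ranged from 4927 to 18155.

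In the comparison of stages, adult glands had more transcript for 3 exopeptidase clusters and for an odorant-binding protein, and nymph glands for a different odorant-binding protein and a cuticle protein. Odorant-binding proteins are small secreted carriers of hydrophobic ligands. Cluster-9520.6260, matching odorant-binding protein 12, was at 1368, 5311 and 791 FPKM in the adult libraries and at 0.68, 0 and 0 in the nymph libraries (log2 fold change 10.72 ± 0.79 SE, limma adjusted p = 0.00039). Cluster-9520.4318, matching odorant-binding protein 2 among proteins and 9 among nucleotide sequences, was at 226, 337 and 270 FPKM in the nymph libraries and at 0, 0.16 and 0 in the adult libraries (log2 fold change -7.91 ± 0.47 SE, limma adjusted p = 9.2e-05). Cluster-9520.6256, unnamed in its first match and matching odorant-binding protein 17 in a further one, was also higher in adults (log2 fold change 8.69, limma adjusted p = 0.0062). It did not pass without nymph replicate 1, 2 or 3 (limma adjusted p = 0.094, 0.055 and 0.059) and was not tested without any adult library.

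Of the exopeptidases, which remove terminal residues, 3 clusters rose in adults. Of the 52 tested members of their list, 36 lay below 0 on the log2 scale. The median of that list was -0.31, close to -0.29 over all tested clusters, so this count is near the general shift. Carboxypeptidase B (Cluster-9520.4052), which removes basic residues from the carboxyl end, was at a rescaled FPKM of 1045.0 ± 795.5 (SD, n = 3) in adults and 2.08 ± 0.484 in nymphs. Its log2 fold change was 7.9 ± 0.78 SE (limma adjusted p = 0.0022). It did not pass without adult replicate 1 (limma adjusted p = 0.05) or without adult replicate 2 (limma adjusted p = 0.083). Aminopeptidase N (Cluster-9520.6270) rose by 6.5 on the log2 scale (limma adjusted p = 0.032). Its limma adjusted p was 0.002 without adult replicate 3 and from 0.17 to 0.27 with any other library left out. Xaa-Pro aminopeptidase P (Cluster-9520.5846) rose by 6.12 (limma adjusted p = 0.014). It did not pass without nymph replicate 1 (limma adjusted p = 0.082) and was not tested without any adult library. Histidine decarboxylase (Cluster-9520.2665), the enzyme that makes histamine, was at 77.4, 1004 and 172 FPKM in adults and listed at 0 in every nymph library (limma adjusted p = 0.00057). The trehalose transporter Tret1 (Cluster-9520.2483), an antibacterial peptide (Cluster-9520.6461), medium-chain acyl-CoA dehydrogenase (Cluster-9520.6264) of fatty acid oxidation and a calcium load-activated calcium channel (Cluster-9520.5170) were higher in adults by 5.47, 5.83, 4.48 and 4.02 on the log2 scale. Their limma adjusted p were 0.0074, 0.026, 0.014 and 0.047. With single libraries left out, the antibacterial peptide passed only without adult replicate 3 (limma adjusted p = 0.039, from 0.056 to 0.18 otherwise). The calcium channel likewise passed only without adult replicate 3 (limma adjusted p = 0.041, from 0.059 to 0.24 otherwise). Medium-chain acyl-CoA dehydrogenase passed only without adult replicate 3 or nymph replicate 3 (limma adjusted p = 0.013 and 0.029, from 0.063 to 0.17 otherwise). Of the 12 clusters higher in adults, 11 had their highest deposited FPKM in adult replicate 2. Without adult replicate 1, and also without adult replicate 2, 7 of the 12 were still tested and 0 passed (limma). Without adult replicate 3, 6 of 7 passed, and without nymph replicates 1, 2 and 3, 5, 6 and 7 of 12.

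Higher in nymphs beside odorant-binding protein 2 were a cuticle protein 6.4 (Cluster-9520.3694) and a cyclin A-associated protein of the endoplasmic reticulum (Cluster-6851.0). The cuticle protein, of a family of structural proteins of the exoskeleton, was at 10.4, 29.2 and 16.6 FPKM in nymphs and listed at 0 in all adult libraries (limma adjusted p = 0.033). Cluster-6851.0 was between 10.9 and 22.0 FPKM in nymphs and listed at 0 in all adult libraries (limma adjusted p = 0.042). Neither the cuticle protein nor Cluster-6851.0 passed without adult replicate 1 or 2 (limma adjusted p = 0.077 and 0.13 for each). Both passed without adult replicate 3, and neither was tested without any nymph library. The other 13 clusters higher in nymphs had no name and were at most 678 bases long. Of all 16 clusters higher in nymphs, 10 were listed at 0 in every adult library and all 16 were listed at 0 in adult replicates 1 and 3, the adult libraries with the fewest clusters detected. Without adult replicates 1, 2 and 3, 4, 1 and 16 of these 16 passed (limma); without nymph replicates 1, 2 and 3, 5 were still tested and 1, 2 and 1 passed.

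In total, 12 of 11961 clusters tested were higher in adults and 16 were lower (limma, adjusted p under 0.05), and all 28 differed at least 2-fold. At an unadjusted p under 0.05 there were 1082. The stages did not overlap in 14.1% of tested clusters, against 10% by chance. The count depended on single libraries: it was 4, 1 and 54 without adult replicates 1, 2 and 3, and 6, 9 and 9 without nymph replicates 1, 2 and 3. The clusters higher in adults among these were 0, 0 and 34, and 5, 6 and 8, and at an unadjusted p under 0.05 they were 247 and 305 without adult replicates 1 and 2. Odorant-binding protein 2 passed without each adult library and odorant-binding protein 12 without each nymph library, and neither reached the filter of 3 libraries when a library of its own higher stage was left out. The count was 72 on FPKM as deposited, 19 after rescaling to an equal total, 12 with a pseudocount of 0.1, 65 with a mean FPKM filter and 104 with no filter.

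**Figure D2:**
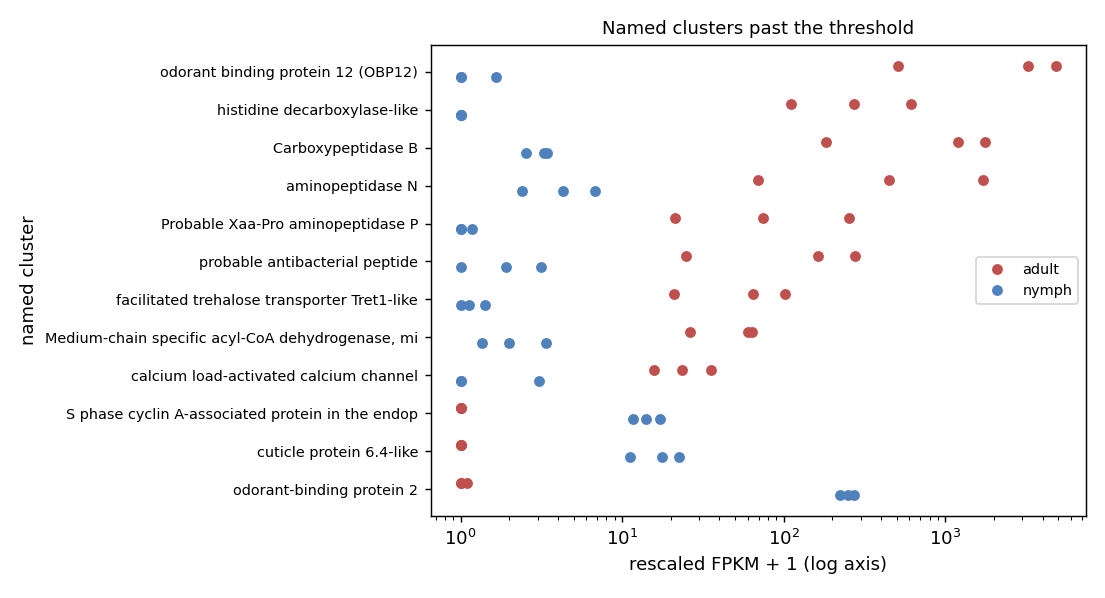
Each row is a named cluster past the threshold. Points are single libraries (adult in red, nymph in blue, 3 each), and the horizontal axis is rescaled FPKM + 1 on a log scale. For odorant-binding protein 12 the adult libraries lie above the nymph libraries, and for odorant-binding protein 2 the order is the opposite.

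Serine proteases, the main enzymes of stink bug venom, lay higher in adults as a list (camera adjusted p = 8.5e-05; adjusted p = 0.77 with an estimated correlation and 0.054 after quantile normalization). None of the 82 tested members passed the threshold over all genes, and 15 rose and 5 fell when adjusted over the list alone. The 3 members named next were chosen after their values were seen. Cluster-9520.4173 was at a rescaled FPKM of 8247 ± 6196 (SD, n = 3) in adults and 468.1 ± 177.5 in nymphs, and Cluster-9520.5262 at 3175 ± 2326 and 194.7 ± 85.0. Cluster-9520.3948 went the other way, at 159.2 ± 18.9 in adults and 1064 ± 316 in nymphs (limma adjusted p over the list alone = 0.0094). Serine proteases took 2.21%, 32.5% and 3.9% of total FPKM in the adult libraries and 2.98%, 10.5% and 3.0% in the nymph libraries (exact permutation p = 0.7, n = 3 per stage). Their 2 most abundant clusters were short, at 383 and 451 bases, so these shares of FPKM are not shares of fragments. Host mitochondrial clusters were at their lowest share, 18.6%, in adult replicate 2, where serine proteases were at their highest.

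None of the other venom lists shifted as a whole at the main setting. Members named for a call over the list alone were chosen after their values were seen. Of 52 metalloproteases and exopeptidases tested, 3 rose and 0 fell over all genes and when adjusted over the list alone (camera adjusted p = 0.64). Alpha-amylase clusters, of a starch-digesting enzyme, had the highest mean FPKM over the 6 libraries among glycosidases, a mean carried by adult replicate 2. Cluster-9520.2779 was at 266, 10644 and 333 FPKM in adults and 73.5, 141 and 28.5 in nymphs, and Cluster-9520.2778 at 303, 7741 and 162 in adults and 134, 55.5 and 13.5 in nymphs. The glycosidase list of 54 had 0 calls over all genes and 1 fall adjusted over the list alone, myrosinase 1 (Cluster-9520.3861) at 1.36, 12.8 and 6.78 FPKM in adults and 232, 92.7 and 36.4 in nymphs (camera adjusted p = 0.21). Over 20 other settings that p ran from 0.015, without nymph replicate 1 and higher in adults, to 0.94, and library quality weights gave 0.034. Of those 20 settings, 3, library quality weights among them, were chosen after seeing the data, here and for the other lists. Of 22 pore-forming and named venom proteins, 1 rose, venom allergen 5 (Cluster-9520.2254), and 3 fell when adjusted over the list alone (camera adjusted p = 0.19). Over 20 other settings that p ran from 0.0071 to 0.55, lower in adults, with 0.02 without adult replicate 1, 0.039 without nymph replicate 3 and 0.55 without nymph replicate 1. Cluster-9520.4202, matching the assassin bug toxin U-reduvitoxin-Pr1a, was at 685, 34.9 and 76.0 FPKM in nymphs and at 0, 0.55 and 3.69 in adults (limma adjusted p = 0.052), and was among the 3 with a serine carboxypeptidase (Cluster-8976.0) and a troponin C (Cluster-6680.0), a muscle protein. The most abundant protease inhibitors were venom Kazal domain peptide 1 (Cluster-9520.1981) at a mean of 54.2 FPKM and a cystatin (Cluster-9520.6364) at 85.5, and the list of 14 had no calls (camera adjusted p = 0.6).

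Cathepsins L1 (Cluster-9520.4327) and D (Cluster-9520.4167), lysosomal proteases, were highest in nymph replicate 1, at 1683 and 1215 FPKM, and at 65.6 and 84.4 in nymph replicate 3. Of 42 cysteine and aspartic proteases, 2 other cathepsins, D (Cluster-9520.1944) and L (Cluster-9520.6348), rose adjusted over the list alone, both chosen after their values were seen (camera adjusted p = 0.34). The direction of that list changed with single libraries: it lay lower in adults without adult replicate 1 (adjusted p = 0.0057) and without nymph replicate 2 (adjusted p = 0.0027), and higher without adult replicate 3 (adjusted p = 0.35) and without nymph replicate 1 (adjusted p = 0.28). Over 20 other settings the adjusted p ran from 1.7e-05 to 0.97. Esterase FE4 (Cluster-9520.6247) was at a rescaled FPKM of 74.9 ± 83.8 (SD, n = 3) in adults and 1.27 ± 0.619 in nymphs (limma adjusted p = 0.065), and was the 1 of 55 lipases, phospholipases and esterases that rose adjusted over the list alone (camera adjusted p = 0.71). Venom carboxylesterase-6 (Cluster-9520.4537) was at 5.78, 10.7 and 71.3 FPKM in adults and 76.3, 65.0 and 61.0 in nymphs. The 12 nucleases and nucleotidases, led by ribonuclease Oy (Cluster-9520.3400) and deoxyribonuclease TATDN1 (Cluster-9520.3786), had no calls (camera adjusted p = 0.7).

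Secretory pathway transcripts lay higher in adults as a list, with 46 of 55 members above 0 on the log2 scale (camera adjusted p = 2.2e-07; adjusted p = 0.44 with an estimated correlation). The chaperone BiP (Cluster-9520.2561) was at 62.0, 649 and 53.6 FPKM in adults and 34.4, 25.6 and 12.1 in nymphs, and translocon-associated protein beta (Cluster-9520.3999) at 27.5, 158 and 211 and at 66.2, 195 and 127. No member passed over all genes or over the list alone. Cytosolic ribosomal proteins lay lower in adults, with 84 of 88 below 0 (camera adjusted p = 0.0011; adjusted p = 0.77 with an estimated correlation and 0.069 without nymph replicate 2), and again no member passed. Of the 114 clusters in that list, 18 were in the noctuid or mouse sets, and without both sets the camera adjusted p was 0.012. S20 (Cluster-9520.4112) and S2 (Cluster-9520.4743) led that list at rescaled FPKM of 522.6 and 357.9 in adults and 767.6 and 629.4 in nymphs. Neither the 37 proteasome members, led by 26S regulatory subunit 8 (Cluster-9520.4460) and alpha type-1 (Cluster-9520.3439), nor the 112 respiratory chain members had a call (camera adjusted p = 0.3 and 0.84). Over 20 other settings the proteasome lay lower in adults with a camera adjusted p from 0.004 to 0.78, at 0.013 without nymph replicate 1. The respiratory chain ran from 0.02, without adult replicate 1 and lower in adults, to 0.99. It lay higher in adults at the main setting and turned direction in 10 of the 20, also without nymph replicate 1 (adjusted p = 0.63) and without nymph replicate 2 (adjusted p = 0.89).

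Cuticle and chitin transcripts lay lower in adults, with all 19 tested members below 0 (camera adjusted p = 1.1e-09; adjusted p = 0.43 with an estimated correlation and 0.31 without nymph replicate 1). Over all genes 1 fell, and 10 fell when adjusted over the list alone. Obstructor-E (Cluster-10443.0), a chitin-binding protein, was at 51.1, 8.37 and 5.36 FPKM in nymphs and listed at 0 in adults, while Cluster-9520.4362, named protein gar2 by its first match and a cuticle protein by a further one, was at 85.6, 65.2 and 60.5 in nymphs and 6.94, 9.52 and 78.5 in adults. Of the 49 clusters in the list, 5 were in the noctuid or mouse sets. Cell cycle and DNA replication lay lower in adults as well, with 38 of 45 below 0 (camera adjusted p = 9.8e-07; adjusted p = 0.44 with an estimated correlation and 0.19 with a filter at FPKM 5) and 7 falls adjusted over the list alone. Chosen after its values were seen, proliferating cell nuclear antigen (Cluster-9520.3769), the sliding clamp of DNA polymerase, was at 9.65, 13.1 and 15.2 FPKM in nymphs and 0, 0.51 and 5.07 in adults. By the rule, BUB3 (Cluster-4395.0) and a kinetochore-associated protein (Cluster-9520.1591) were the most abundant members. BUB3 was at 44.3 and 16.4 FPKM in nymph replicates 2 and 3, listed at 0 elsewhere and not tested, and the kinetochore protein was at a log2 fold change of 1.62.

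Detoxification lay lower in adults, with 63 of 78 below 0 (camera adjusted p = 4.3e-05; adjusted p = 0.71 with an estimated correlation and 0.31 without nymph replicate 1), and 1 rise, cytochrome P450 4C1 (Cluster-9520.2214, chosen after its values were seen), and 7 falls adjusted over the list alone. Its most abundant members went apart: glutathione S-transferase 1 (Cluster-9520.4279) was at 45.7, 1006 and 113 FPKM in adults and 145, 89.1 and 36.1 in nymphs, and isoform D (Cluster-9520.4370) at 21.0, 50.5 and 66.2 and at 539, 153 and 149. Ecdysone and juvenile hormone genes also lay lower in adults (camera adjusted p = 0.0025; adjusted p = 0.43 with an estimated correlation, 0.072 without adult replicate 3, 0.061 without nymph replicate 1 and 0.26 with a filter at FPKM 5). Of 27, 1 fell adjusted over the list alone, a Niemann-Pick C2 protein (Cluster-9695.0, chosen after its values were seen), while the receptor E75 (Cluster-9520.2710) was at a log2 fold change of 0.03. Chemosensory proteins had 2 rises and 1 fall over all genes, the odorant-binding proteins above, and 3 rises and 4 falls of 18 adjusted over the list alone, among them an odorant receptor (Cluster-9520.2505) and odorant-binding protein 4 (Cluster-9681.0), chosen after their values were seen. As a list they lay in no fixed direction (camera adjusted p = 0.7), lower in adults without adult replicate 1 (adjusted p = 0.028) and higher without nymph replicate 1 (adjusted p = 0.00072), 2 (adjusted p = 0.05) or 3 (adjusted p = 0.013). They also lay lower without adult replicate 2 (adjusted p = 0.16) and 3 (adjusted p = 0.15), with a range up to 0.85 over 20 other settings. The members tested changed with the filter of 3 libraries. Odorant-binding protein 12 and Cluster-9520.6256 were not tested without any adult library, nor odorant-binding protein 2 without any nymph library. These turns of direction therefore do not compare the same members. Heat shock proteins, led by cognate 4 (Cluster-9520.4412) and heat shock protein 83 (Cluster-9520.4639), had no call among 53 (camera adjusted p = 0.3).

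Of the markers of other tissues, haemocytes and immunity lay higher in adults (camera adjusted p = 3.5e-05; adjusted p = 0.44 with an estimated correlation). Over all genes 1 of 31 rose, the antibacterial peptide, a call that held only without adult replicate 3 when single libraries were left out. Adjusted over the list alone 7 rose, among them, chosen after their values were seen, the peptidoglycan-cleaving B-type lysozyme (Cluster-9520.2617) and spaetzle (Cluster-9520.2317), a ligand of Toll receptors. The most abundant members were serine proteases matching phenoloxidase-activating enzymes, Cluster-9520.4471 and Cluster-9520.4452. Cluster-9520.4452 is named venom serine protease 34-like and is also in the serine protease list. The shifts of these lists are therefore not independent, and this list is not a clean marker of haemocytes. Muscle had no call among 50 (camera adjusted p = 0.057, lower in adults). Over 20 other settings that p ran from 0.00013 without adult replicate 1 to 0.45 without adult replicate 2, with 0.024 without adult replicate 3 and 0.038 without nymph replicate 2, and 11 of the 20 passed. Muscle actin (Cluster-9520.4603) was at 38.3, 115 and 103 FPKM in adults and 234, 276 and 391 in nymphs and muscle-specific protein 20 (Cluster-9520.5242) at 23.4, 47.4 and 32.1 and at 109, 60.4 and 141. Fat body and haemolymph proteins, led by transferrin (Cluster-9520.3214) and apolipoprotein D (Cluster-9520.1396), had 3 falls of 13 adjusted over the list alone (camera adjusted p = 0.15). Over 20 other settings that camera adjusted p ran from 0.0069 without adult replicate 1 to 0.43 without nymph replicate 3. The falls, chosen after their values were seen, were in hexamerin (Cluster-9520.5895), apolipophorins (Cluster-10830.1) and an arylphorin (Cluster-8943.0) that belongs to the moth set. Neurons, led by a voltage-dependent anion-selective channel (Cluster-9520.4149) and synaptic vesicle glycoprotein 2B (Cluster-9520.2656), had no call (camera adjusted p = 0.65). The channel entered that list through the words voltage-dependent in its name and is not a marker of neurons. Germ line and gonad, led by a cilia- and flagella-associated protein (Cluster-9520.6014) and an axonemal dynein (Cluster-9126.0), had no call either (camera adjusted p = 0.42).

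**Figure D3:**
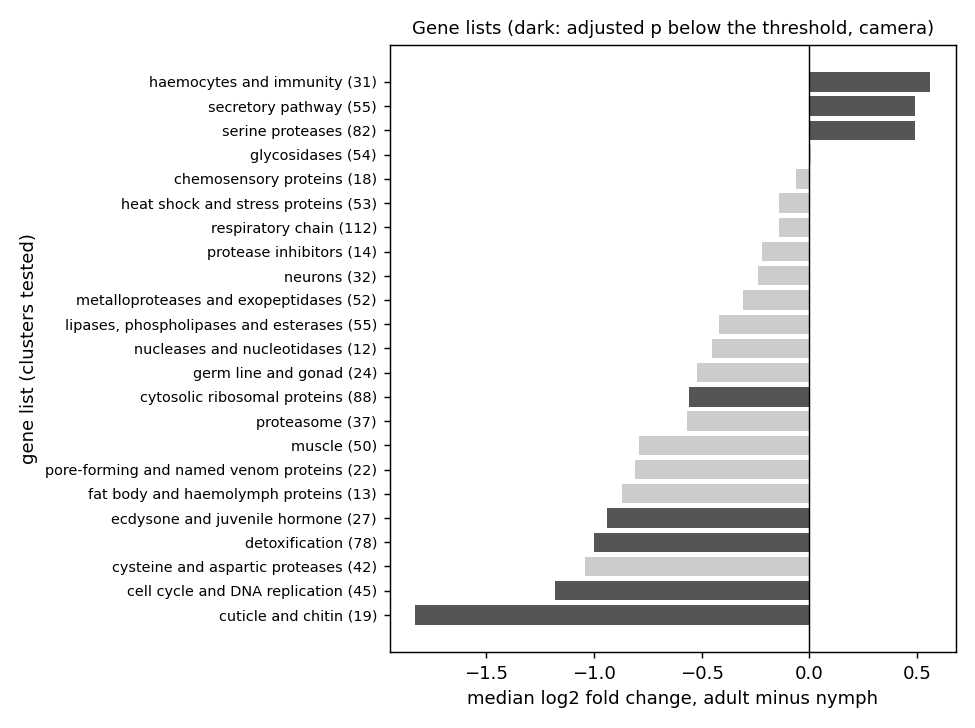
Bars give the median log2 fold change, adult minus nymph, over the tested members of each gene list, whose number is in parentheses. Dark bars mark the 8 lists past the threshold with camera at its preset correlation, of which 3 lay higher and 5 lower in adults, and none of the 8 passed with an estimated correlation.

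For the share of total FPKM, none of the 23 lists could pass (exact permutation test, adjusted p from 0.767 to 1.0), because the design cannot give a p under 0.1. The test thus cannot decide whether shares differ. For cuticle and chitin and for muscle the stages did not overlap, lower in adults, with the smallest possible unadjusted exact permutation p of 0.1. By chance 10% of lists would show this. The median log2 fold change over all tested clusters was -0.29, and -0.02 after quantile normalization, so the direction of a list is relative to that shift. The 8 lists past the threshold kept their direction under each scaling, while the camera direction differed in sign from the median of the members for chemosensory proteins, heat shock proteins, lipases, protease inhibitors and the respiratory chain, and from their mean for glycosidases. The lists lower in adults were not separated from the low detection in adult replicates 1 and 3. Chosen after their values were seen, polo kinase (Cluster-11759.0) and cytochrome P450 3A19 (Cluster-8285.0) were listed at 0 in all adult libraries. Cell cycle still passed without adult replicate 1 (camera adjusted p = 6.1e-06) or 3 (2.5e-05), and leaving out both was not tested.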

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

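Library quality weights were chosen after seeing the data. The 28 clusters that differed, all at least 2-fold, became 12 with a pseudocount of 0.1, 104 with no filter, 65 with a mean FPKM filter, 72 on FPKM as deposited and 65 with library quality weights; the cause was not tested. Leaving out single libraries gave 1 to 54 clusters, with fewer samples and a filter still asking for 3 libraries. That filter also changed which members of a list were tested. No cluster among the 28 was called in the opposite direction under these settings, and 28 were shared on FPKM as deposited, 28 with weights and 12 with a pseudocount of 0.1. Rescaling to an equal total called 19 clusters, of which 14 were among the 28. Limma-voom on recovered fragments called 29; of the 28, 8 were shared, 11 did not pass and 9 under 400 bases were not tested. The 8 shifted lists became 15 after rescaling to an equal total, 13 with weights and 8 to 14 without single libraries, the 14 without adult replicate 1. With an estimated correlation or with fry 0 lists passed, and at an unadjusted p under 0.05 there were 2 and 6. Lists with a higher mean share in adults numbered 7, and 2 to 13 without single libraries, 2 without adult replicate 2 and 13 without adult replicate 1.

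Replicate numbers are shared between stages. Deviations from the stage means correlated at 0.165, -0.0427 and 0.213 for numbers 1, 2 and 3. Between adult and nymph libraries of unlike number they correlated from -0.275 to 0.151. With 3 libraries per stage these values cannot decide whether the numbers pair the libraries. With a replicate block 29 clusters were called, 15 higher and 14 lower in adults, of which 22 were among the 28, and 8 lists shifted. At least 13334175 fragments were recovered per library, and on simulated data with the observed spread 22 of 50 clusters changed 16-fold were recovered for adult minus nymph.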

Other observations

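The tests of depth, of moth and mouse matches and of other splits, and the control on nymph replicate 1, were chosen after the result was seen. The tests on thinned libraries were set before. All clusters named below were chosen after their values were seen. Virus-like RNA was abundant in the glands and differed between libraries within each stage. Cluster-9520.4848, 10544 bases long and matching a viral RNA1 polyprotein, was at 20864, 7792 and 8.7 FPKM in adult replicates 1, 2 and 3 and at 2.03, 40669 and 37044 in nymph replicates 1, 2 and 3. FPKM divides by length, so at equal FPKM this cluster holds far more fragments than Cluster-9520.4356, a mitochondrial cluster of 458 bases. Its FPKM therefore understates its load on a library, and the effect of that load on the stage comparison was not tested. Cluster-9520.5175 and Cluster-9520.5076, matching a viral genome polyprotein, were at 1348 and 915 FPKM in nymph replicate 3, at 5.76 and 0.75 in nymph replicate 2 and listed at 0 in the other libraries.

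Adult replicates 1 and 3 detected fewer clusters than adult replicate 2. Lower depth is argued against, since their fitted totals of mapped fragments were 0.965 and 1.29 times that of adult replicate 2. Loss to mitochondrial RNA is argued against as the whole cause: adult replicate 2, thinned to their fragments outside the mitochondrial clusters, still detected 2.23 and 1.8 times as many clusters. Those fragments include virus-like RNA. Cluster-9520.4848, 10544 bases long, was at 20864 FPKM in adult replicate 1, 7792 in adult replicate 2 and 8.7 in adult replicate 3. For adult replicate 1 the ratio of 2.23 therefore cannot exclude loss to virus-like RNA, which was not tested. Few distinct molecules copied many times may be a source, and cannot be told apart here. The share of detected clusters at 1 or 2 fragments was 0.215 and 0.0566 times that of thinned adult replicate 2, within the bound set for this explanation, but nymph replicate 1, which detected 12673 clusters against 15116 in thinned adult replicate 2, gave 0.0733 and nymph replicate 3 gave 0.957, so a low value also occurs without the loss and the test does not decide; a biological difference was not tested.

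Clusters matching noctuid moths, a family that includes prey of this bug, were detected more often in nymphs, with 70, 50 and 36 against 2, 18 and 3 in adults. Unequal detection of all clusters is argued against, because the lowest nymph library had 2.77 times as many per 1000 other clusters as the highest adult library. RNA of prey in the nymph samples may be the source, a difference in feeding between stages being untested, which cannot be told apart from chance with 3 libraries per stage (exact permutation p = 0.1, the smallest possible). Against a simple reading, Cluster-10091.0, matching moth mitochondrial cytochrome oxidase, was at 1005, 16.9 and 856 FPKM in adults and 25.9, 350 and 697 in nymphs. Without moth and mouse clusters, 32 clusters differed between stages and 8 lists shifted.

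Clusters matching mouse were detected mainly in nymph replicate 1, with 52 of 56, against 11, 32 and 6 in adult replicates 1, 2 and 3 and 5 and 3 in nymph replicates 2 and 3. Their summed FPKM was 658.3 in nymph replicate 1 and 469.7, 66.8 and 126.3 in adult replicates 1, 2 and 3, of which 319 in adult replicate 1 came from Cluster-9520.7707, matching testin. Whether they are conserved bug transcripts cannot be decided by detection. The set had already left out clusters with a best protein match in Hemiptera, which removes many such transcripts beforehand. Mouse-matching clusters detected in nymph replicate 1 were detected in 19.6% of cases per other library. That was 0.449 times the 43.7% of other clusters matched on nymph replicate 1 FPKM and length, and below the lowest of 1000 matched draws, 34.6%. Other comparisons computed earlier gave 7.14% against 58.7% in nymph replicates 2 and 3, and a ratio of 0.647 in adult replicate 2. Mouse RNA in the libraries may be the source and cannot be told apart from other sources, since the values that go with it had been seen before the test, with 92.3% of the 13 mouse mitochondrial clusters highest in nymph replicate 1 and prolactin-3B1 (Cluster-11482.0), a placental hormone, at 18.9 FPKM there and listed at 0 elsewhere. No biological explanation was tested.

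The 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split gave 28 clusters, at any fold and at 2-fold, and the highest other split 8, and 1 of 10 splits gave as many. For the lists the real split gave 8 and the highest other 10, and 3 of 10 splits gave as many.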
